A study of Mus musculus with 12 samples.

How the data were processed

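The series profiled 12 RNA samples from stable lines of 4T1, a mouse mammary carcinoma cell line, on Affymetrix Mouse Gene 1.0 ST arrays, which measure transcripts with sense-strand targets and many probes per gene. Per the labels there were 4 lines with 3 arrays each. These are a control line and lines named for Mkl1 constructs, FL, mutB1 and ΔSAP. Mkl1, now called Mrtfa, is an actin-regulated coactivator of serum response factor (Srf). All cultures were held in 0.03% serum for 48 h before RNA extraction, and 100 ng of total RNA per sample was amplified, per the labels' protocols. The series design text describes triplicate cultures. The labels name a single stable line per construct, so a difference between constructs cannot be separated from a difference between lines. The p-values of single probe sets rest on the spread between cultures of the same line. Tests of gene lists against other genes, and of overlaps, take genes or probe sets as units. No p-value here measures a spread between independent lines of a construct.

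The deposited values are log2 expression values per probe set, made by the authors with RMA (background correction, quantile normalization and probe summarization). Per the series design text this was done with the affy package of Bioconductor 2.4, and the submitters' processing notes name R 2.10.0 and affy. The probe set definition, scan dates, array batches and genome build are not given in the sources used here. RMA values have no detection call, and a signal near the low end of the scale may be background. The median log2 value of an array lay between 6.35 and 6.46. For arrays of this kind the precision is limited by their number, here 3 per line.

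The table held 34760 probe sets. GEO's platform annotation, dated 2016, gave 21640 of them exactly 1 gene symbol, 1321 several symbols and 11799 none. The single-symbol probe sets covered 19937 distinct genes, of which 954 had more than 1 probe set. Symbols were updated through Entrez identifiers with a RefSeq gene table of assembly GRCm38.p6, which matched 21553 of the single-symbol probe sets and left 87 with the name in the annotation. That table was used for names only, and no coordinates are printed. A gene with several probe sets is represented by the one with the highest mean over the 12 arrays. Names were not taken from probe sets with several symbols, so a list member without a probe set of its own was not analysed here.

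Differences between lines were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in a single fit of all 12 arrays with the 4 line means, with Benjamini-Hochberg adjustment over all 34760 probe sets. A probe set was counted as changed under the filters of the series design text: adjusted p of at most 0.01, a fold of at least 2 and a mean log2 value of at least 4, taken here over all 12 arrays, a filter that 30212 probe sets passed. The comparisons named in the design text, FL against mutB1 and FL against ΔSAP, are the main comparisons. The other 4 pairs of lines and an F test over the 4 lines were run in the same fit. Every change is the first line minus the second on the log2 scale, with its standard error (SE). Means are given with the standard deviation (SD) of 3 arrays. The ΔSAP against mutB1 comparison tests whether the main comparisons differ from each other.

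Classes of genes were formed from these calls: changed the same way in both main comparisons, changed against mutB1 with a called difference between ΔSAP and mutB1 in the same direction, and changed against ΔSAP with a called difference between ΔSAP and mutB1 in the opposite direction. Because the main comparisons share the FL arrays, 20 sets of unchanged arrays were simulated to give the correlation and covariance that shared arrays produce.

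In all, 26 gene lists were fixed before the data were examined. They cover Srf and Mrtf cytoskeletal and contractile targets, growth-factor immediate early genes, YAP-TEAD targets, matricellular and matrix proteins, extracellular proteases, integrins and focal adhesion, epithelial junctions and keratins, mesenchymal transition, mitosis, DNA replication, interferon response, MHC class I presentation, NF-kB and inflammatory cytokines, cholesterol synthesis, glycolysis and hypoxia, unfolded protein and amino acid response, p53 targets, TGF-beta response, oxidative stress response, ribosomal proteins, actin regulators, mammary differentiation, and markers of fibroblasts, leukocytes, endothelium and adipocytes. A list member rose or fell where its adjusted p over all probe sets was at most 0.01, with no minimum fold. The number of members adjusted over the list alone stands beside it. Each list was tested as a set in each of the 6 comparisons with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 156 list comparisons, with an adjusted p of at most 0.05 as the call. Of these, 60 were called. With the correlation estimated from the data 17 of them stayed called, and p-values from that form are given beside the calls that it ended among those reported. The fry test, which asks only whether a set moves on balance one way, called 104.

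The genes named were chosen by a rule fixed in advance. It took the 12 largest rises and 12 largest falls in each main comparison and the 5 largest each way in the other comparisons and in each class, with every array of the first line above, or every array below, all arrays of the second. It also took up to 4 members of each list by adjusted p, or the 2 brightest where none passed, and always Mrtfa, Mrtfb, Srf, Tnc, Acta2, Tagln and Vcl. Symbols of predicted genes and bare accessions were counted but not named. Where any other gene is named, the text says that it was chosen after its values were seen.

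The fit was tested on simulated data on the same 34760 probe sets. In the simulated FL against mutB1 comparison, 92% of genes with a true log2 change of 1.5 were called, 92% of those with a change of 2, and 52% of those with a change of 1, which lies at the fold filter. No unchanged probe set was called, and 1 passed on adjusted p alone. Alternatives tried were a replicate block, median centring, a further quantile normalization, an intensity trend with a robust prior, array weights, fits of only the lines compared, other filters and thresholds, treat, leaving out each array in turn, and other set tests. No per-sample columns were left unused, and no pair of arrays held the same values.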

Results

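Expression was measured in 4 stable 4T1 mouse mammary carcinoma lines, with 3 arrays per line: a control line and lines named FL, mutB1 and ΔSAP for Mkl1 constructs. FL is read here as full-length Mkl1. The B1 region of Mkl1 is known for binding serum response factor, and the SAP domain is a putative DNA-binding motif that the series design sets against the full-length line. Arrays of the same line correlated at r = 0.995 to 0.997 across probe sets, and arrays of different lines at 0.988 to 0.995. A line mean under 6.35, the lowest median of an array, is called low here, a level chosen after the values were seen. Its signal may be background, so a change against a low mean is the measured difference, may understate the true one, and ranks only as measured. The first principal component held 34.8% of the variance and separated the FL and ΔSAP arrays from the control and mutB1 arrays, and the second held 22.5% and separated the mutB1 arrays from the others.

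Mkl1 itself (Mrtfa, probe set 10430693) was raised in every construct line. Its log2 value was 9.27 ± 0.01 (SD, n = 3) in the control line, 12.08 ± 0.06 in FL, 11.29 ± 0.11 in mutB1 and 11.92 ± 0.04 in ΔSAP. In limma, the rise over control was 2.81 ± 0.06 (SE, adjusted p = 3.67e-10) in FL, 2.01 ± 0.06 (adjusted p = 3.12e-09) in mutB1 and 2.65 ± 0.06 (adjusted p = 7.5e-10) in ΔSAP. The mutB1 line held less Mkl1 RNA than the FL line, by 0.79 ± 0.06 (limma adjusted p = 2.79e-06), whereas FL and ΔSAP differed by 0.16 (limma adjusted p = 0.0776). The positions of the probes relative to the altered parts of the constructs were not checked, so these levels need not compare equally across constructs. Mrtfb, the close relative of Mkl1, and Srf passed the threshold in none of the comparisons at their brightest probe sets, with limma adjusted p of 0.588 and 0.0984 between FL and mutB1. A dimmer Mrtfb probe set was 0.19 higher in ΔSAP than in mutB1 (limma adjusted p = 0.0055).

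Tenascin-C (Tnc), a matricellular protein of the tumour stroma, stood at 5.83 ± 0.11 in control, 7.76 ± 0.20 in FL, 6.29 ± 0.06 in mutB1 and 7.70 ± 0.20 in ΔSAP (SD, n = 3). FL exceeded mutB1 by 1.47 ± 0.12 (limma adjusted p = 6.78e-06) and control by 1.94 ± 0.12 (adjusted p = 7.14e-07), and FL and ΔSAP differed by 0.07 ± 0.12 (adjusted p = 0.782). The Tnc means in control and mutB1 were low. Smooth muscle actin (Acta2), a contractile target of Srf, was higher in FL than in mutB1 by 0.36 ± 0.06 (limma adjusted p = 0.000948) and lower in FL than in ΔSAP, where the change was -0.36 ± 0.06 (adjusted p = 0.00165). The Acta2 means in control and mutB1 were also low (6.20 and 6.26), so its change between FL and mutB1 may be understated. Vinculin (Vcl) was 0.19 ± 0.04 higher in FL than in mutB1 (limma adjusted p = 0.00548). Tagln passed in none of the comparisons, but its mean was low in every line, from 5.15 in control to 5.32 in ΔSAP. The Tagln signal may be background, so the absence of a call does not show that Tagln was unchanged.

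**Figure D1:**
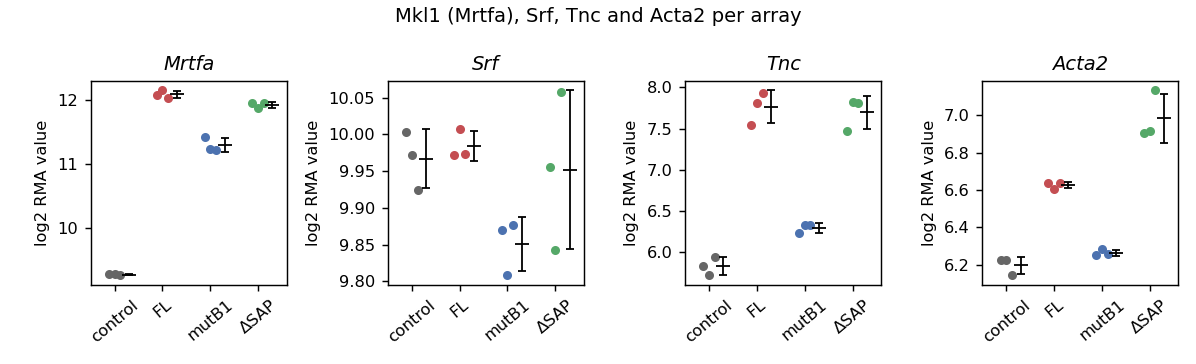
Log2 RMA values (vertical axis) of Mrtfa (Mkl1), Srf, Tnc and Acta2 in each array of the 4 lines (horizontal axis), with points for single arrays and a dash with bars for the mean ± SD of 3 arrays beside them. Vertical axes differ between panels and do not start at 0. Mrtfa was above control in all 3 construct lines, and Tnc was near 7.7 in FL and ΔSAP and near 6 in control and mutB1.

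The first main comparison, FL against mutB1, addresses which genes depend on the B1 region of overexpressed Mkl1. Epithelial adhesion genes were higher in the FL line. Krt7, a keratin of simple epithelia, was 5.51-fold higher, Cdh1 (E-cadherin) 4.68-fold higher and the desmosomal gene Dsp 5.97-fold higher. Dsg2, a desmosomal cadherin, stood at 9.03 in FL and at a low 5.85 in mutB1. In the opposite direction, Srgn, the proteoglycan serglycin, was 15.7-fold lower in FL, and Pdgfrb, the PDGF receptor beta of mesenchymal cells, was 15.5-fold lower, to a low mean of 6.33. Cholesterol synthesis genes were lower in FL (adjusted p = 0.168 with an estimated correlation) and genes of the unfolded protein and amino acid response were higher (adjusted p = 0.0339 with an estimated correlation).

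The largest rises in FL over mutB1 were Lncenc1 (3.88 ± 0.05, SE, n = 3 arrays per line), the cyclin Ccnd2 (3.37 ± 0.09), Dsg2 (3.18 ± 0.07), Serpinb9b, Tmprss11e, the cytokine Il1a, Mal2, Serpinb6b, the tight junction gene Cldn9, Macc1, mesothelin (Msln) and Cd74, the invariant chain, which rose by 2.69 ± 0.08. The limma adjusted p of these 12 lay between 6.43e-11 and 5.07e-08. The largest falls were Srgn (-3.98 ± 0.09), Pdgfrb (-3.96 ± 0.10), Kank4, Gpc4, the lipopolysaccharide-binding protein Lbp, the laminin Lama4, Itih2, the alarmin Il33, Synpo2, the hyaluronan-binding Cemip, the focal adhesion gene Tns1 and Inmt (-2.36 ± 0.11), with limma adjusted p between 8.13e-10 and 1.43e-07. In the line with the lower value the mean was low for Lncenc1, Dsg2, Il1a, Mal2, Macc1 and Cd74 among the rises and for Pdgfrb, Kank4, Gpc4, Lama4, Itih2, Il33, Synpo2 and Inmt among the falls. Of the other Tns1 probe sets, 4 of 5 passed in the same direction. Serpinb9b and Serpinb6b belong to a family of near copies, and their probes may share signal.

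Of 29 epithelial junction and keratin genes, 16 rose and 3 fell in FL against mutB1 (18 and 3 adjusted over the list alone), with a median change of 0.59 (limma camera adjusted p = 6.59e-10, and 0.04 with an estimated correlation). Krt7 rose by 2.46 ± 0.04, Dsp by 2.58 ± 0.06, Cdh1 by 2.23 ± 0.04 and Cldn4, a tight junction claudin, by 1.91 ± 0.04. Among 28 NF-kB target and cytokine genes, 14 rose and 4 fell (17 and 4 adjusted over the list alone). The list passed camera in limma (adjusted p = 0.000174) and with an estimated correlation (adjusted p = 0.032). The neutrophil chemoattractant Cxcl5 rose by 1.82 ± 0.06, the growth factor Csf3 by 1.42 ± 0.04 and the adhesion molecule Icam1 by 1.33 ± 0.04, whereas Il33 fell by 2.72 on the log2 scale. Of 28 unfolded protein and amino acid response genes, 22 rose and 1 fell (22 and 2 adjusted over the list alone), among them the stress transcription factor Ddit3 (1.56 ± 0.04) and the endoplasmic reticulum genes Sdf2l1 (1.06 ± 0.05) and Herpud1 (0.85 ± 0.04). This list had a median of 0.43 (limma camera adjusted p = 2.89e-11, and 0.0339 with an estimated correlation).

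All 20 measured cholesterol synthesis genes fell in FL against mutB1, as did all 20 adjusted over the list alone, with a median of -0.60. The list passed camera in limma (adjusted p = 1.95e-14), and the call was lost when the correlation was estimated (adjusted p = 0.168 with an estimated correlation). Tm7sf2 changed by -1.14 ± 0.04, Pmvk by -1.04 ± 0.06, Hsd17b7 by -1.03 ± 0.06 and Lss by -0.74 ± 0.05, all enzymes of the pathway. Of 22 TGF-beta response genes 13 fell and 0 rose (13 and 0 adjusted over the list alone), led by Id1 (-1.13 ± 0.04), Tgfbr1, Smad7 and Inhba (limma camera adjusted p = 0.000483, and adjusted p = 0.179 with an estimated correlation). Of 20 mesenchymal transition genes, 8 fell and 2 rose (9 and 2 adjusted over the list alone), with Pdgfrb, Pdgfra (-1.49 ± 0.06), Sparc and Itgb3 in the lead (limma camera adjusted p = 0.00572, and adjusted p = 0.137 with an estimated correlation).

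Of 25 mitosis genes 11 fell and 1 rose in FL against mutB1 (15 and 2 adjusted over the list alone), including Mki67 (-0.39) and Aurka (-0.31), and of 28 replication genes 10 fell and 0 rose (11 and 1 adjusted over the list alone), including E2f1 (-0.33). Both passed camera in limma (adjusted p = 0.00527 and 0.00679), with adjusted p = 0.53 and 0.42 with an estimated correlation. The interferon list had 8 of 25 members up, such as Oas2 (0.90) and Rsad2 (0.70), and 0 down, with the same counts adjusted over the list alone (limma camera adjusted p = 0.003, and adjusted p = 0.633 with an estimated correlation). Of 29 immediate early genes 12 rose and 4 fell (12 and 5 adjusted over the list alone), with Dusp5 up by 1.19 and Egr2 changed by -1.27 (limma camera adjusted p = 0.0196, and adjusted p = 0.444 with an estimated correlation).

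The Srf and Mrtf cytoskeletal list had 11 of 38 members higher and 5 lower in FL than in mutB1 (12 and 5 adjusted over the list alone), and its median was 0.09. Camera in limma gave an adjusted p of 0.032, with adjusted p = 0.188 with an estimated correlation. The call also ended after median centring (adjusted p = 0.0737), after a further quantile normalization (0.0608), without FL replicate 2 (0.0623) and without mutB1 replicate 3 (0.0505). Actn1 (0.31) and Smtn (0.31) were higher, and Cald1 (-0.53) and Zyx (-0.28) lower.

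The remaining lists did not pass camera in FL against mutB1 (limma adjusted p between 0.107 and 0.969). YAP-TEAD targets had 2 of 22 higher and 7 lower (Rbms3 -1.10, Ccn2 -0.62). Matrix genes had 5 of 32 higher and 12 lower (Lamb3 1.21, Ccn5 -1.12), and proteases had 9 of 29 higher and 7 lower (Plaur 0.90, Adamts9 -2.25). Integrins and focal adhesion had 7 of 25 higher and 8 lower (Fermt1 2.02, Cav1 1.04). MHC class I had 1 of 9 higher and 1 lower (Tap2 0.21, Psmb10 -0.30), and glycolysis and hypoxia 9 of 26 higher and 7 lower (Adm 1.80, Aldoc -1.06). p53 targets had 8 of 17 higher and 4 lower (Perp 2.57, Sesn1 -1.37), and the oxidative stress list 7 of 21 higher and 2 lower (Hmox1 1.39, Gstm1 -1.30). Ribosomal proteins had 1 of 24 higher and 0 lower (Rpl27 0.22, not shared by its other 2 probe sets). Actin regulators had 6 of 30 higher and 4 lower (Capg 0.49, Sdc4 -0.58) and mammary differentiation 4 of 18 higher and 3 lower (Erbb3 1.28, Gata3 -0.46). Markers of other cell types did not pass camera, though fry called the fibroblast (adjusted p = 2.56e-06) and leukocyte markers (adjusted p = 0.00279) lower in FL. Of the fibroblast markers 1 of 14 was higher and 4 lower, all 4 by at least 2-fold (Fbln1 -1.61). Of the leukocyte markers 1 of 16 was higher and 2 lower (Cd68 1.05, S100a8 -1.57). Of 12 endothelial markers 0 were higher and 1 lower (Eng -0.33), and 0 of 7 adipocyte markers passed (Plin1 -0.05). Adjusted over the list alone, the counts higher and lower became 5 and 13 for matrix genes, 12 and 7 for proteases, 7 and 9 for integrins, 2 and 2 for MHC class I, 9 and 8 for glycolysis and 0 and 0 for ribosomal proteins, and were the same for the others.

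In all, 556 probe sets changed between FL and mutB1, 338 higher and 218 lower in FL, which stand for 257 and 180 distinct genes. Without the fold filter, 6126 probe sets passed the other filters in limma. With a minimum mean of 6 in place of 4, Lama4 was no longer called. Set against the control line, FL lay beyond control on its side of the difference at 237 of the 556, mutB1 lay beyond control on the other side at 139, both did at 5, and neither was called at 175. Each construct is represented by a single line, and the mutB1 line held less Mkl1 RNA, so the comparison cannot by itself assign a gene to the B1 region.

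**Figure D2:**
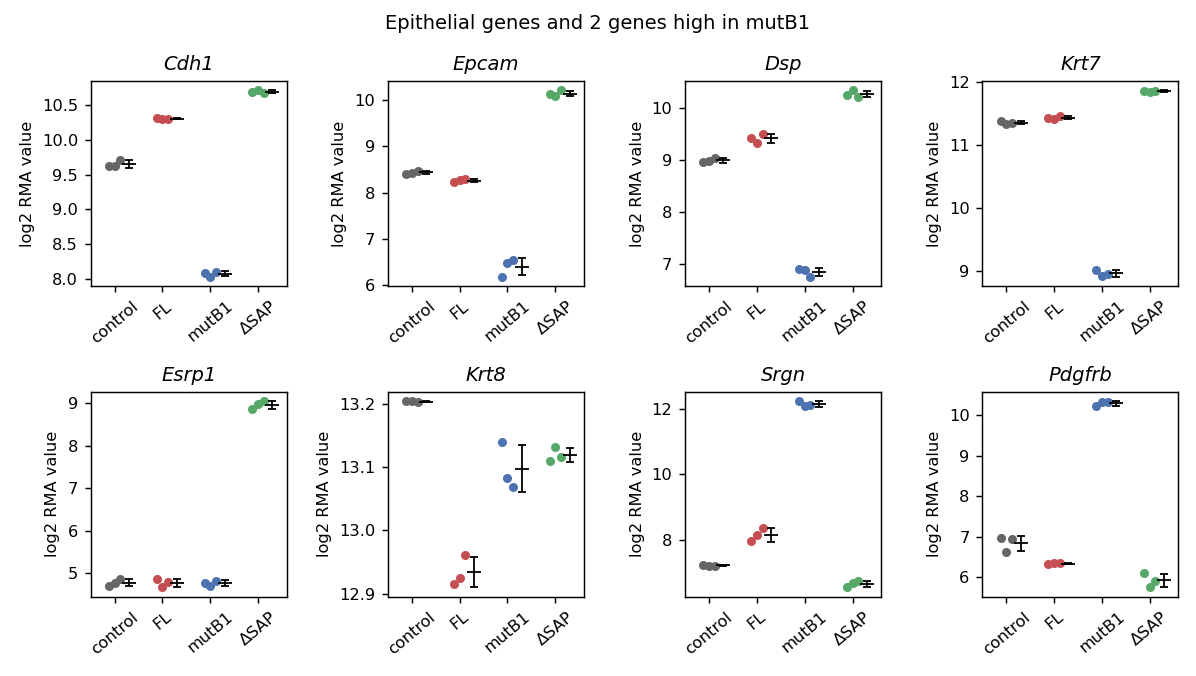
Log2 RMA values (vertical axis) of the epithelial genes Cdh1, Epcam, Dsp, Krt7, Esrp1 and Krt8 and of Srgn and Pdgfrb in each array of the 4 lines (horizontal axis), with points for single arrays and a dash with bars for the mean ± SD of 3 arrays beside them. Vertical axes differ between panels and do not start at 0. Cdh1 lay near 8.08 in mutB1 and 10.69 in ΔSAP, Esrp1 stood above 8 in ΔSAP alone, and Srgn and Pdgfrb were highest in mutB1. Krt8 was chosen for the plot after its values were seen.

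The second main comparison, FL against ΔSAP, addresses which genes depend on the SAP domain. Epcam, an epithelial adhesion molecule, was 3.68-fold lower in FL than in ΔSAP. Esrp1, an epithelial splicing regulator, stood at 8.97 ± 0.09 in ΔSAP (SD, n = 3) against low means of 4.77 in FL, 4.78 in control and 4.76 in mutB1. Interferon response genes were higher in FL (adjusted p = 0.215 with an estimated correlation), with the antiviral GTPase Mx1 up 3.91-fold and the antiviral enzyme Rsad2 up 2.23-fold. Cholesterol synthesis genes were lower in FL, as against mutB1 (adjusted p = 0.0958 and 0.168 with an estimated correlation). Stress response genes were higher in both comparisons (adjusted p = 0.0261 and 0.0339 with an estimated correlation). Mkl1 RNA itself differed little between these lines.

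The largest rises in FL over ΔSAP were Trim30d (2.21 ± 0.12, SE, n = 3 arrays per line), the arsenic methyltransferase As3mt (2.00 ± 0.09), Mx1 (1.97 ± 0.11), the transcription factor Osr1, the carbonic anhydrase Car6, Ifi44l, Iigp1 and Gbp4 of the interferon response, the imprinted gene Mest, Serpinb9b, Ccnd2 (1.61 ± 0.09) and Serpinb6b. Their limma adjusted p lay between 1.2e-07 and 2.15e-05. The largest falls were Esrp1 (-4.19 ± 0.07), Pate9, Tmem54 (-3.17 ± 0.13), Kctd12b, the carboxypeptidase Cpm (-3.01 ± 0.06), Pate14, the serine protease Prss22, Nipal2, Mid2, the acid phosphatase Acpp, the coagulation factor gene F13a1 and Tbc1d30, with limma adjusted p between 2.67e-10 and 1.16e-06. In the line with the lower value the mean was low for Trim30d, Car6, Esrp1, Pate9, Kctd12b, Cpm, Mid2, Acpp and Tbc1d30. Mx, Gbp, Trim30 and Pate genes have close relatives whose probes may share signal.

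Of 29 epithelial genes 16 fell and 1 rose in FL against ΔSAP (16 and 2 adjusted over the list alone), with a median of -0.20. Camera in limma gave an adjusted p of 2.99e-08, with adjusted p = 0.0512 with an estimated correlation. Esrp1, Epcam (-1.88 ± 0.08), Cldn4 (-1.26 ± 0.04) and the junction gene Jup (-0.56 ± 0.04) led them. Of 25 interferon genes 18 rose and 0 fell (20 and 0 adjusted over the list alone), with a median of 0.46, among them Rsad2 (1.16 ± 0.06), Gbp3 (0.79 ± 0.04) and Bst2 (0.61 ± 0.04). Camera in limma gave an adjusted p of 4.24e-13, with adjusted p = 0.215 with an estimated correlation. Of 9 MHC class I genes 5 rose and 0 fell (6 and 0 adjusted over the list alone), including the proteasome subunit Psmb8 (0.66 ± 0.06) and the peptide transporter Tap1 (0.59 ± 0.05) (limma camera adjusted p = 1.13e-05, and adjusted p = 0.0519 with an estimated correlation). Of 28 NF-kB and cytokine genes 12 rose and 3 fell (17 and 3 adjusted over the list alone), with Icam1 (1.57 ± 0.04) and the monocyte chemoattractant Ccl2 (1.45 ± 0.05) up and Il33 changed by -1.37 (limma camera adjusted p = 4.34e-05, and 0.0266 with an estimated correlation).

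Of the 20 cholesterol synthesis genes 19 fell and 0 rose in FL against ΔSAP, with the same counts adjusted over the list alone and a median of -0.57. Hmgcs1, an early enzyme of the pathway, changed by -0.88 ± 0.06, Hsd17b7 by -0.80 ± 0.06 and Lss by -0.76 ± 0.05 (limma camera adjusted p = 2.05e-20, and adjusted p = 0.0958 with an estimated correlation). The unfolded protein and amino acid response had 22 of 28 members up and 0 down (25 and 0 adjusted over the list alone), including Ddit3 (1.15 ± 0.04), Sdf2l1 (0.93 ± 0.05), Sesn2 (0.84 ± 0.05) and Cth (0.74 ± 0.04), with a median of 0.37 (limma camera adjusted p = 2.61e-16, and 0.0261 with an estimated correlation). Of 22 TGF-beta response genes 11 fell and 1 rose (12 and 1 adjusted over the list alone), with Inhba (-0.86 ± 0.05), Pmepa1 (-0.51) and Id3 (-0.48) down (limma camera adjusted p = 5.78e-05, and adjusted p = 0.13 with an estimated correlation). Integrin and focal adhesion genes had 7 of 25 down and 3 up, including Fermt1 (-1.57 ± 0.05) and Itgb4 (-0.76), with the same counts adjusted over the list alone, and matrix genes 11 of 32 down and 2 up (12 and 2 adjusted over the list alone), including the collagens Col4a2 (-0.51) and Col4a1 (-0.39). Both passed camera in limma (adjusted p = 0.000786 and 0.00473), with adjusted p = 0.466 and 0.32 with an estimated correlation.

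The other lists did not pass camera in FL against ΔSAP (limma adjusted p between 0.0996 and 0.945). The Srf and Mrtf cytoskeletal list had 5 of 38 members higher and 3 lower in FL, with the same counts adjusted over the list alone and a median of 0.01 (limma camera adjusted p = 0.918). Flnc was 0.69 higher, and Tpm2 changed by -1.09 and Actg2 by -0.65. Immediate early genes had 6 of 29 higher and 5 lower (Atf3 0.62, Egr3 -0.48), and YAP-TEAD targets 5 of 22 higher and 4 lower (Ankrd1 0.38, Rbms3 -0.63). Proteases had 3 of 29 higher and 4 lower (Mmp9 0.65, Plat -0.79), and mesenchymal transition 0 of 20 higher and 3 lower (Foxc2 -0.97). Mitosis had 2 of 25 higher and 3 lower, and replication 1 of 28 higher and 1 lower (Mcm2 0.33, Uhrf1 -0.21). Glycolysis and hypoxia had 6 of 26 higher and 6 lower (P4ha2 0.80, Car9 -1.29), and p53 targets 3 of 17 higher and 4 lower (Plk2 0.74, Perp -0.84). The oxidative stress list had 5 of 21 higher and 2 lower (Hmox1 0.75, Gsta4 -0.48), and mammary differentiation 0 of 18 higher and 4 lower (Erbb3 -1.55, Csn3 -0.89). Ribosomal proteins had 1 of 24 higher, and actin regulators 4 of 30 higher and 1 lower (Limk1 0.34, Cttn -0.28). Fibroblast markers had 1 of 14 higher and 1 lower (Dcn 0.49), and leukocyte markers 1 of 16 higher (S100a8 0.53). Endothelial markers had 2 of 12 higher, and adipocyte markers 0 of 7. Adjusted over the list alone, the counts higher and lower became 7 and 5 for immediate early genes, 5 and 5 for YAP-TEAD targets, 1 and 4 for mesenchymal transition, 8 and 3 for oxidative stress, 4 and 2 for actin regulators, 1 and 4 for mammary differentiation and 2 and 1 for fibroblast markers, and were the same for the others.

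In all, 175 probe sets changed between FL and ΔSAP, 75 higher and 100 lower in FL, standing for 53 and 88 distinct genes, and 3959 passed the other filters in limma without the fold filter. With a minimum mean of 6 in place of 4, Esrp1, Pate9, Mid2 and Trim30d were no longer called, and Tpm2 was not called by treat against a fold of 1.5 (adjusted p = 0.0511). Of the 75 higher in FL, 67 were also higher in FL than in control, and 32 were higher in ΔSAP than in control as well. Of the 100 lower in FL, 50 were higher in ΔSAP than in control and 35 were lower in FL than in control. A single line stands for each construct here too.

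Genes changed the same way in both main comparisons numbered 58 probe sets, 33 higher and 25 lower in FL. By the smaller of the changes, the leading rises were Osr1, Car6, Serpinb9b, Ccnd2 and Serpinb6b. The leading falls were Cpm, the heparan sulfatase Sulf2 (-2.29 ± 0.04 against mutB1 and -1.74 ± 0.04 against ΔSAP), the angiotensin-converting enzyme Ace (-2.05 ± 0.06 and -1.65 ± 0.06), Acpp and Il33. Independent lists of these sizes would share 0.839 higher and 0.722 lower. A further 20 probe sets changed in opposite directions. Fisher's exact test of the overlap took shared calls in either direction, these 20 included (p = 3.89e-88). The changes in both comparisons correlated at 0.348 across probe sets, against 0.5 from the shared FL arrays alone in simulation, and their covariance was 0.0291 against 0.00698 simulated. With 3 FL arrays the shared line could not be split, so part of the excess overlap may come from the shared arrays.

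A further 266 probe sets changed against mutB1, not against ΔSAP, with a called difference between ΔSAP and mutB1, 161 of them higher in FL. Lncenc1, Dsg2, Il1a, Cldn9 and Macc1 led the higher group, with ΔSAP exceeding mutB1 by 3.51 for Lncenc1 and 3.75 for Cldn9, and Pdgfrb, Kank4, Lbp, Lama4 and Gpc4 led the lower group. The class changed against ΔSAP alone, with mutB1 also differing from ΔSAP, held 61 probe sets, 20 higher and 41 lower in FL. Mx1, Iigp1, the coagulation inhibitor Tfpi (1.43 ± 0.06), the nucleic acid sensor Zbp1 (1.28 ± 0.05) and Ccrl2 (1.20 ± 0.08) led the higher group, and Esrp1, Tmem54, Pate9, Prss22 and Nipal2 the lower.

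Against the control line, interferon response genes rose in each construct line. With an estimated correlation the adjusted p was 0.0519 in FL, which ended that call, 0.0462 in mutB1 and 0.0466 in ΔSAP. All 25 measured members rose in FL, in mutB1 and in ΔSAP, with median changes of 2.33, 2.02 and 1.69, and the same counts held adjusted over the list alone. Ifit3 rose by 4.14 ± 0.07 in FL, 3.72 ± 0.07 in mutB1 and 3.18 ± 0.07 in ΔSAP (SE, n = 3 arrays per line), and Oas2 by 4.24 ± 0.08 in FL. Camera in limma gave adjusted p of 1.55e-31, 4.25e-37 and 3.57e-36. MHC class I genes rose with them, 9 of 9 in FL, 8 in mutB1 and 8 in ΔSAP (9, 8 and 9 adjusted over the list alone), with Tap1 up by 1.81 ± 0.05 in FL and 1.93 ± 0.05 in mutB1 (limma camera adjusted p = 5.75e-09, 1.77e-10 and 1.19e-07). Leukocyte markers did not pass camera, with 1 of 16 higher in FL, 1 in mutB1 and 0 in ΔSAP. By fry they were higher in mutB1 (adjusted p = 0.00466) and lower in ΔSAP (adjusted p = 0.00324).

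FL differed from control at 636 probe sets, 420 higher and 216 lower. Ifi44l, Oas2, Ifit3b, Ifit3 and Mx2 rose most, and Lbp (-3.85 ± 0.12), Inmt, Cpm, Il33 and Sned1 fell most. The control means of Ifi44l, Ifit3b and Mx2 and the FL means of Inmt, Cpm and Il33 were low. Of 29 epithelial genes 10 rose and 4 fell in FL against control (11 and 6 adjusted over the list alone), with a median of 0.02, and the list did not pass (limma camera adjusted p = 0.187). The stress list rose in 24 of 28 members and fell in 1, with the same counts adjusted over the list alone, with Ddit3 up by 1.78 ± 0.04 (limma camera adjusted p = 1.72e-17, and 0.0261 with an estimated correlation), and 18 of 20 cholesterol genes fell with 0 rising (19 and 0 adjusted over the list alone; limma camera adjusted p = 5.75e-09, and adjusted p = 0.274 with an estimated correlation). The stress list also rose against control in the other construct lines, with 15 members higher and 2 lower in mutB1 and 17 higher and 3 lower in ΔSAP. Adjusted over the list alone these were 18 and 2, and 18 and 3. Camera in limma gave an adjusted p of 1.06e-07 in mutB1 and 5.75e-09 in ΔSAP, with adjusted p = 0.0605 and 0.05 with an estimated correlation. mutB1 differed from control at 419 probe sets, 249 higher and 170 lower, led by Srgn (4.90 ± 0.09), Iigp1, Ifi44l, Gpc4 and Zbp1 upward and Osr1 (-3.21 ± 0.07), Rps6ka6, Perp, Tnik and Tubb2b downward. The control means of Iigp1, Ifi44l and Gpc4 and the mutB1 mean of Rps6ka6 were low. In mutB1, 15 of 29 epithelial genes fell and 0 rose, also when adjusted over the list alone, with Krt7 changed by -2.38 ± 0.04, Dsp by -2.15 ± 0.06 and Cdh1 by -1.58 ± 0.04 (limma camera adjusted p = 3.02e-11, and 0.0339 with an estimated correlation), and 25 of 28 replication genes rose, including Ccne1 (0.98) and Tyms (0.61) (26 adjusted over the list alone; limma camera adjusted p = 1.9e-16, and 0.0339 with an estimated correlation). Of 14 fibroblast markers 3 rose and 1 fell in mutB1 against control, with the same counts adjusted over the list alone, a mean change of 0.48 and a median of -0.01, which differ in sign (limma camera adjusted p = 0.157, fry adjusted p = 3.97e-06). Pdgfrb went from 6.84 in control to 10.29 in mutB1. Replication genes were also higher than control in the other construct lines, with 17 of 28 rising and 1 falling in FL (17 and 1 adjusted over the list alone) and 19 rising and 0 falling in ΔSAP (19 and 0 adjusted over the list alone). Camera in limma gave an adjusted p of 1.71e-07 in FL and 4.36e-11 in ΔSAP, with adjusted p = 0.126 and 0.0519 with an estimated correlation.

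ΔSAP differed from control at 467 probe sets, 333 higher and 134 lower. Fermt1, an integrin activator, rose by 5.15 ± 0.05, followed by Nipal2, Mal2 (4.41 ± 0.07), Pate14 and Esrp1 (4.19 ± 0.07), and Lbp (-4.18 ± 0.12), Osr1, Inmt, Ccn5 and Synpo2 fell most. The control means of Fermt1, Nipal2, Mal2, Pate14 and Esrp1 were low, as were the ΔSAP means of Inmt and Synpo2. Of 29 epithelial genes 16 rose and 0 fell in ΔSAP (16 and 0 adjusted over the list alone; limma camera adjusted p = 5.19e-09, and 0.0462 with an estimated correlation). The Srf and Mrtf cytoskeletal list had 8 of 38 members higher and 2 lower in FL than in control (8 and 2 adjusted over the list alone), with a median of 0.04 that became -0.01 when each array was centred on its median (limma camera adjusted p = 0.025, and adjusted p = 0.168 with an estimated correlation). That centring ended the call (adjusted p = 0.0658), as did a further quantile normalization (adjusted p = 0.0541). ΔSAP and mutB1 differed at 495 probe sets, 307 higher and 188 lower in ΔSAP, with Tmprss11e, Mal2, Esrp1, Tmem54 and Pate14 highest and Srgn (-5.47 ± 0.09), Pdgfrb, Kank4, Lbp and Cemip lowest. The mutB1 means of Mal2, Esrp1, Tmem54 and Pate14 and the ΔSAP means of Pdgfrb, Kank4 and Cemip were low. Of 14 fibroblast markers 1 was higher and 4 lower in ΔSAP than in mutB1, with the same counts adjusted over the list alone (limma camera adjusted p = 0.0523, and adjusted p = 0.444 with an estimated correlation). The F test over the lines found 1166 probe sets. Higher than control in all 3 construct lines were 131 probe sets of 87 genes, 22 of them interferon list members, and lower in all 3 were 24 probe sets of 22 genes. FL and ΔSAP shared 211 higher and 95 lower calls against control (4.63 and 0.958 for independent lists), and their changes had a covariance of 0.0952 against 0.00703 simulated from the shared control arrays. FL and mutB1 shared 170 higher and 35 lower calls (3.46 and 1.22 for independent lists; covariance 0.0635 against 0.00712 simulated), and mutB1 and ΔSAP shared 143 and 27 (2.74 and 0.754; covariance 0.0454 against 0.00708). The correlations of these pairs, in the same order, were 0.766, 0.531 and 0.435, against 0.501, 0.506 and 0.504 simulated. For mutB1 and ΔSAP the correlation thus lay under the simulated value. The 3 control arrays could not be split, so part of each overlap may come from them.

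**Figure D3:**
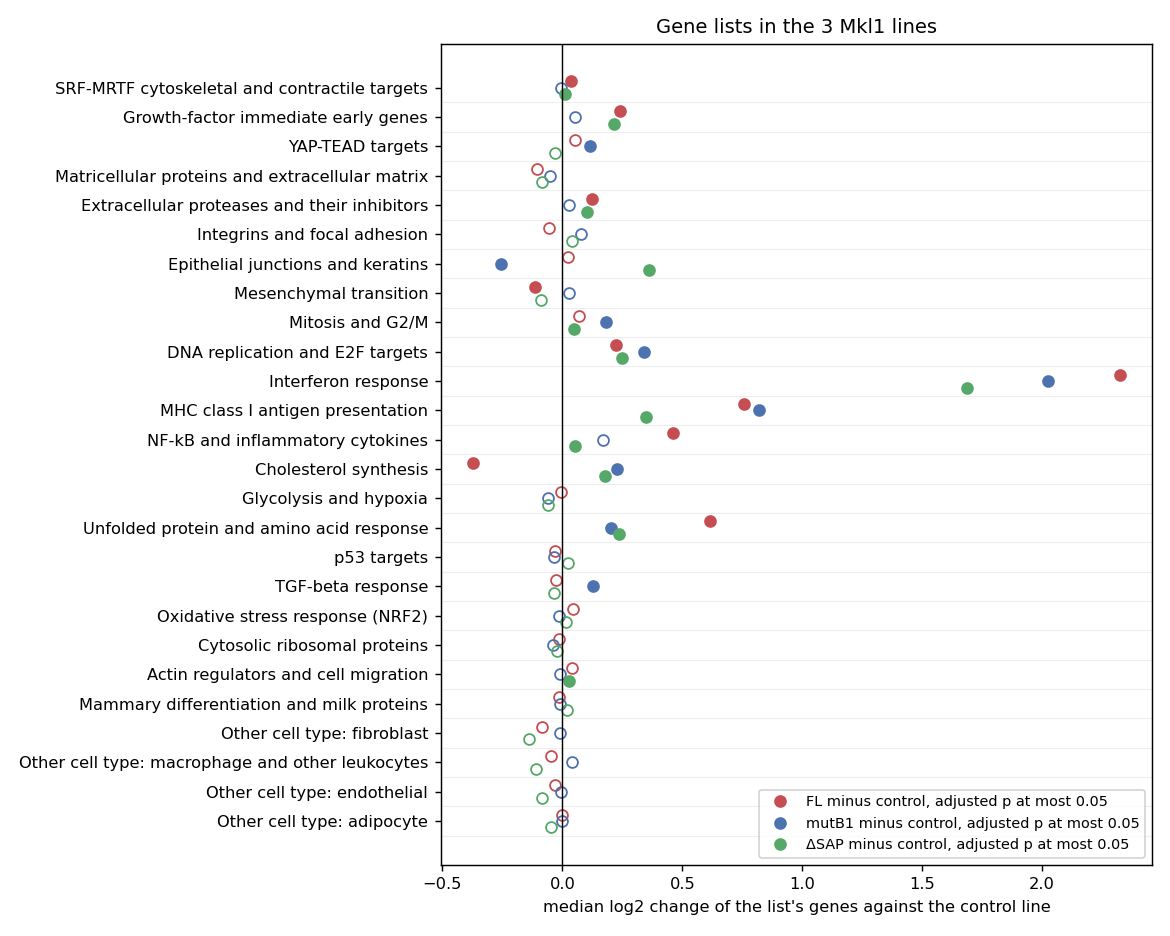
Median log2 change against the control line (horizontal axis) of each of the 26 gene lists (vertical axis) in the FL, mutB1 and ΔSAP lines. Filled points passed limma's camera at an adjusted p of at most 0.05 with the preset correlation, open points did not, and no error bars are drawn. The interferon response lay between 1.69 and 2.33 in all 3 lines, the epithelial list at -0.26 in mutB1 and 0.36 in ΔSAP, and cholesterol synthesis at -0.37 in FL and above 0 in the other lines.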

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

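The tests of the interferon genes and of the mutB1 genes beyond the control level were chosen only after those results were seen. The predictions of the other tests here were written before their outcomes were seen. The fatty acid and LXR lists were not among the 26 fixed in advance, and were drawn up to explain the cholesterol result. Groups of 3 arrays are too small for a formal test of single arrays that stand apart, but fits without each array are given below. Without control replicate 2, 733 probe sets differed between FL and control, against 636 with all arrays.

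The epithelial list moved in opposite directions against control in ΔSAP and in mutB1, with medians of 0.361 and -0.255, and the direct comparison of the lines gave a median of 0.852 (limma camera adjusted p = 1.73e-18). In that comparison 4 of 14 fibroblast markers, Pdgfrb, Fbln1, Pi16 and Pdgfra, were at least 2-fold lower in ΔSAP than in mutB1 and 1 was higher, with a mean change of -0.629 and a median of -0.143 (limma camera adjusted p = 0.0523, and adjusted p = 0.444 with an estimated correlation). The fibroblast list passed with array weights (0.0455), median centring (0.0378), an intensity trend (0.0418), only the lines compared (0.0441) and genes of mean under 4 left out (0.0392). It also passed without FL replicate 1 (0.0482), control replicate 2 (0.0458), ΔSAP replicate 1 (0.028), mutB1 replicate 1 (0.0499) or mutB1 replicate 2 (0.0431). Against control, the cholesterol synthesis list had 18 of 20 members lower in FL, 11 higher in mutB1 and 9 higher in ΔSAP, and passed limma camera in each, though with adjusted p = 0.274, 0.321 and 0.508 with an estimated correlation. Its median was -0.372 in FL against 0.228 in mutB1 (difference -0.601, limma camera adjusted p = 1.95e-14) and 0.178 in ΔSAP (difference -0.573, limma camera adjusted p = 2.05e-20). These differences had adjusted p = 0.168 and 0.0958 with an estimated correlation. Between FL and mutB1, 5 probe sets were called in opposite directions against control, with F5, Mpzl2 and Msln among them. Between ΔSAP and mutB1 there were 23, which include the epithelial genes Cdh1, Cldn4, Dsp, Epcam, Krt19, Lad1, Pkp2 and St14. F5, Mpzl2, Krt19, Lad1, Pkp2 and St14 were named after their values were seen.

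All 25 interferon list members were higher than control in each of the Mkl1 lines (adjusted p = 0.0519 in FL, 0.0462 in mutB1 and 0.0466 in ΔSAP with an estimated correlation). Leukocyte RNA is argued against as a cause common to these lines, since at most 1 of 16 markers was called higher in any line. By fry the leukocyte markers were nonetheless higher than control in mutB1 (adjusted p = 0.00466), and lower in ΔSAP (adjusted p = 0.00324). Signal shared within gene families is argued against as the whole cause, since all 11 members without close relatives on the list rose in each line. A response that follows the Mkl1 RNA level whatever the construct stays open: the list was lower in ΔSAP than in mutB1 (median -0.339, 14 members lower and 0 higher), but with adjusted p = 0.445 with an estimated correlation, and the measured Mkl1 levels need not compare equally across constructs. A difference of the single control line from any other line cannot be told apart from an effect of the constructs, since the design holds 1 control line. An effect of Mkl1 itself, or a difference that arose between the stable lines as they were made, may be at work and was not tested further.

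The mutB1 line held less Mkl1 RNA than FL, so weaker overexpression could account for part of the genes that differ between them. A response that only rises or only falls with the Mkl1 level would leave mutB1 between control and FL. Weaker overexpression with such a response is argued against for 144 of the 556 probe sets, or 25.9%. At these, mutB1 lay beyond the control level on the side away from FL. Cdh1, Dsp, Krt7 and Cldn4 were among them, but not Dsg2 (mutB1 against control -0.09, limma adjusted p = 0.52). Whether the response has that form was not tested. For the 237 probe sets at which FL was beyond control and mutB1 was not on the other side, ΔSAP was nearer to FL than to mutB1 at 142, or 59.9%. For these, weaker overexpression cannot be told apart from the loss of the B1 function, since ΔSAP differs from mutB1 in both. A property of the single mutB1 line also stays open for both parts and was not tested.

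The cholesterol synthesis list was lower in FL than in the other lines, with 17 of 20 members lower than in all 3 (adjusted p = 0.168, 0.0958 and 0.274 with an estimated correlation against mutB1, ΔSAP and control). Lower synthesis of lipids under SREBP, the regulator of both pathways, is a candidate explanation that predicts a fall of fatty acid genes: of 15, 11, 8 and 9 were lower in FL than in mutB1, ΔSAP and control, and the smallest excess of lower over higher was 8. The fall was partial: Fasn and Acaca passed in none of these comparisons, and Gpam was 0.29 higher in FL than in mutB1 (limma adjusted p = 0.00307). Fasn, Acaca and Gpam were named after their values were seen. Sterol excess with activation of LXR is argued against only weakly, on 8 targets: 2 were higher and 4 lower in FL than in mutB1, and 1 and 3 than in control. Against ΔSAP 1 was higher and 1 lower, which decides nothing. The smallest excess of higher over lower was -2. Abca1 and Smpdl3a, named after their values were seen, had low means in FL, ΔSAP and control, so their changes may be understated. Both remain hypotheses, and a property of the single FL line stays open.

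For each of the 6 pairs of lines the 10 splits of 6 arrays are too few for a share under 0.05. The real split was the 1 that gave as many probe sets in each pair (556, 175, 636, 419, 467 and 495), and the highest other gave 0. Over the 4 lines, 1 of 100 groupings reached 1166, the real one, with 188 as the highest other, so chance can be excluded for that count. Likewise 1 of 100 groupings reached the 60 shifted lists, but another reached 52. Among 100 groupings of the 9 arrays of the Mkl1 lines, 4 gave as many as the 58 probe sets changed in both main comparisons, the highest other with 325, which points to a structure of the samples. That grouping kept the 3 mutB1 arrays together as a group. For the class changed against mutB1 with a difference, 2 of 100 reached 266 (highest other 321), and for the class changed against ΔSAP with a difference, 3 of 100 reached 61 (highest other 66). Each of these other groupings kept a whole line together, so the shares largely reflect how rarely a random grouping does so. They decide nothing about the classes themselves or about line against construct.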

How the results depend on the processing

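The counts as distinct gene symbols, without the control line, and without interferon and MHC class I members were chosen after the data were seen, and all other alternatives before. No called gene among those named changed sign, and no called list passed in the opposite direction. The median of the Srf and Mrtf list against control did change sign, from 0.037 to -0.014 in FL when each array was centred on its median (adjusted p = 0.0658) and from 0.009 to -0.008 in ΔSAP after a further quantile normalization (adjusted p = 0.102). Centring also turned it below 0 in ΔSAP. The ΔSAP call (adjusted p = 0.0382) was lost with an estimated correlation (adjusted p = 0.2 with an estimated correlation), without ΔSAP replicate 3 (0.0532) and with genes of mean under 4 left out (0.05, above the threshold before rounding). The cause was not tested. Counts of changed probe sets moved by over 1.5 times only with other thresholds. With no fold minimum they were 6126 for FL against mutB1, 3959 for FL against ΔSAP, 6893, 4392 and 5107 for FL, mutB1 and ΔSAP against control, 5168 for ΔSAP against mutB1, 9562 over the 4 lines, 2061 in both main comparisons, and 2280 and 882 in the classes with a difference. At an adjusted p of at most 0.05 and a fold of at least 1.5 they were, in the same order, 1705, 719, 2043, 1137, 1323, 1468, 3431, 305, 742 and 179. With the second comparison at an adjusted p of at most 0.05 without a fold minimum, 304 were changed in both. Looser thresholds admit more by construction. List shifts numbered 17 of 156 with an estimated correlation and 104 by fry, against 60, and the cause of the difference was not tested. The F test has no value under treat or in fits of only the lines compared.

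Leaving out each array in turn gave 522 to 581 probe sets for FL against mutB1, 168 to 179 for FL against ΔSAP, 599 to 733, 403 to 454 and 445 to 516 against control, 467 to 536 for ΔSAP against mutB1, 1120 to 1246 over the lines, 53 to 62 in both, 249 to 294 and 57 to 65 in the classes, 54 to 61 lists, and 2.77 to 2.83 for the Mrtfa change in FL. Of 288 called gene comparisons among the 685 named, 261 stayed called under every alternative run and 27 were lost in at least 1. A minimum mean of 6 ended 12 calls, all of dim genes such as Esrp1, Lama4 and Pate9, and treat ended 5, such as Tpm2 and Cd68. The other alternatives ended 14, such as Cxcl5 in FL against ΔSAP and Gadd45a in FL against mutB1. The alternatives chosen later gave 437, 141 and 45 distinct symbols for the main comparisons and both, 560, 180 and 62 probe sets without the control line, and 556, 172 and 58 without members of the interferon and MHC class I lists. Interferon genes off those lists, such as Ifi44l, Iigp1 and Gbp4, stayed in these counts. Signals near the low end of the scale limit what can be seen of dim genes.

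Replicate numbers do not pair the arrays: the 18 same-number pairs had a median r of -0.0206 (-0.231 to 0.184), 2 were above 0.1, and 0 arrays correlated best with their own number throughout. With the replicate number as a block the counts were 549, 175, 627, 423, 464 and 494 for the pairs of lines in the order above for FL against mutB1, FL against ΔSAP, the 3 lines against control and ΔSAP against mutB1, and 60 lists.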

Other observations

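The tests of the stress arms below were chosen only after the result was seen. Genes outside the rule, namely Mthfd2, Wars, Nars, Ddit4, Hspa5, Acly, Scd1 and Fasn, were named after their values were seen. Chac1 and Asns come under the rule in comparisons against control, and were picked out here after their values were seen.

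Asparagine synthetase (Asns) was 0.57 higher in FL than in mutB1, 0.58 higher than in ΔSAP and 1.41 higher than in control. The glutathione-degrading enzyme Chac1 exceeded control by 1.73 in FL, and the mitochondrial folate enzyme Mthfd2 by 1.80. In limma at an adjusted p of at most 0.01, 13 of 15 genes of an amino acid arm under the transcription factor Atf4 rose against control and 0 fell, with 11 rising against mutB1 and 11 against ΔSAP. A further list of 18 tRNA synthetases and other Atf4 targets had 17 higher and 1 lower in FL than in control, and included the synthetases Nars (0.77) and Wars (0.54). In mutB1 against control 11 of the 15 and 15 of the 18 were higher and 0 and 1 lower, the lower one being Wars (-0.23, limma adjusted p = 0.00117). In ΔSAP 9 and 14 were higher and 0 lower. No set test was run on these lists. The chaperone Hspa5 was 0.50 higher in FL than in control. Of 12 endoplasmic reticulum chaperone genes 11 rose in FL in each comparison taken singly, not always the same ones, and 10 rose against all 3 lines. Among fatty acid genes, Scd1 changed by -0.41 and Acly by -0.29 in FL against mutB1, whereas Fasn (0.13, limma adjusted p = 0.0288) did not pass.

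A hypothesis is that the rise of the stress list in FL includes an amino acid response through Atf4. If so, Atf4 targets outside the stress list should be higher in FL than in all 3 other lines. This held for 13 of the 18 genes of the further list, none of them on the stress list, or 72.2%, which is consistent with that response taking part. Another of the 18, Ddit4, went against the prediction. It was lower in FL than in mutB1, ΔSAP and control (-0.41, -0.29 and -0.29, limma adjusted p = 0.000308, 0.00457 and 0.00294). Of the 15 genes of the Atf4 arm, 9 were higher in FL than in all 3 other lines, but all 15 are on the stress list and decide nothing. The same holds for a load on the endoplasmic reticulum, since all 12 chaperone genes are on the stress list and the 83.3% of them higher in FL than in all 3 restate it, so that explanation stays open. With a single FL line, the response could belong to that line.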
